A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

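The series holds 6 libraries of budding yeast (Saccharomyces cerevisiae). The DNA libraries come from Replicon-seq: 2 from wild-type cells (WT) and 2 from cells labelled rrm3. Per the labels, the helicase subunit MCM4 was fused to micrococcal nuclease, so that adding calcium cut DNA where replisomes stood. Cells were arrested in G1 with alpha factor, released at 25 °C into 400 µg/mL BrdU, a thymidine analogue, and collected after 30 min. Long molecules were read on nanopore flow cells. The other 2 libraries hold RNA from WT cells labelled with 4-thiouracil for 15 min, starting 15 min after release, enriched for mRNA and read as cDNA. Groups were taken from the sample titles. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

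The deposited files list aligned reads, with a chromosome, a start and an end for each, and no header. Per the submitters' processing notes, reads were aligned with minimap2, and its version is not given in the sources used here. The labels name DNAscent as the tool that found BrdU. In the DNA files the authors' column of values per read, which no header names, is a fraction from 0 to 1, and most values are ratios of small whole numbers. It was read as the share of a read's windows with BrdU. In the RNA files the deposited score per alignment is a whole number from 31 to 60, as a mapping quality would be, and it was not used to filter reads. The cut-off behind BrdU calls and the genome build are not given in the sources used here.

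The build was compared with a gene table of assembly R64. On 8 of the 16 chromosomes the last gene of that table ended beyond the reads, and the files hold a separate rDNA contig. Positions are therefore given as in the files, counted from 1, and no position from the gene table was used. The gene table served only for the number of genes per chromosome and for the chromosome and length of RRM3. Named genes, tRNA genes, centromeres, LTRs and annotated origins could not be placed on the reads, and the comparisons planned for them, with the preset gene lists, were not run. The classes used in their place were found in the files: origin candidates, RNA segments, segments near chromosome ends and random positions. The design of each test was otherwise kept as fixed before the data were examined.

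For every read name the longest row was used. Reads on the 16 nuclear chromosomes with a BrdU fraction above 0 were taken as replicon reads. Their number was 119544 and 143872 in WT and 129064 and 168538 in rrm3, out of 921386, 1274684, 970733 and 1265591 nuclear reads. The left end of a read was taken as a cut at a leftward replisome and the right end as a cut at a rightward one. Files consisted of 2 or 3 sorted sections each, which may be sequencing runs, and these were compared as a check. Replicates of a group differed by more than sampling noise, with a chi-square over its degrees of freedom of 1.23 in WT and 1.34 in rrm3 across 10151 bins, so no library was counted as a copy of another.

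Read ends were counted in bins of 500 bp, for both directions together and for left and right ends apart. The log2 ratio of each bin to the mean of its surroundings, 1000 to 5000 bp away on each side, was taken with a pseudocount of 0.5 ends. Bins needed a mean of at least 10 ends over the 4 libraries. The last 10000 bp of each chromosome and positions 440001 to 504000 of chromosome 12, around the place of the rDNA, were left out. Windows around features reached 250 bp to each side and were compared with flanks of 1000 to 3000 bp. Segments near chromosome ends ran from 300 to 3000 bp from the end and were compared with the stretch 5 to 10 kb from it. Ratios were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend), 2 libraries against 2, with Benjamini-Hochberg adjustment over all bins of one kind, or over all features of all classes, at 0.05. Classes were compared with all other features by camera, with a preset and with an estimated correlation. Values per library were compared by a two-sided exact permutation test, which with 2 against 2 cannot go below p = 0.333.

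Origin candidates were peaks in the density of midpoints of BrdU reads of 2 to 40 kb, smoothed with an SD of 500 bp and averaged over the 4 libraries. A peak had to reach 3 times the genome mean and be the highest within 5 kb. Enrichment of midpoints was the density within 500 bp of a candidate over that 3 to 5 kb away. Left and right arms were the lengths from a candidate to the ends of a read that spanned no other candidate, each arm at least 500 bp. Controls were 1000 seeded random positions at least 2 kb from a candidate. RNA segments were stretches of at least 500 bp covered by at least 20 RNA reads on one strand, and a read counted for the segment that held its middle. Levels are CPM of nuclear reads. Segments of the plus strand had right read ends in a narrow place, with a median of 70.5% of them in the fullest 50 bp against 38.2% of left ends, so the strand column was read as the strand of the transcript. The 275 segments with the highest RNA formed the RNA class. On the rDNA contig, read ends of rows with BrdU were counted in bins of 250 bp, leaving out the first and last bin.

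The bins named in the text were the 5 with the largest change in each direction outside the classes, and for other classes up to 3 in each direction. The 10 RNA segments with the highest mean were named too. The RRM3 place and the rDNA were always reported.

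The bin test was tested on simulated data, with counts drawn from the real bin means and library sizes and 200 changed bins. For both directions together it ran on 10261 bins, with 2 false calls among 73. It recovered 96.0% of 50 tested bins raised 4-fold, 10.0% of 50 raised 2-fold and 57.1% of 28 lowered 4-fold. All bins raised 4-fold passed the filter on counts, but not all of those lowered 4-fold did, so falls were harder to call. For left ends, on 4453 bins, 92.0% of bins raised 4-fold were recovered, with 5 false calls among 65 (7.69%). For right ends, on 4352 bins, 98.0% were recovered, with 4 false calls among 78 (5.13%). Alternatives covered window, flank and bin sizes, the pseudocount, the filter on counts, limma-voom, read length, rows per read (planned for results other than bins), the replicate block and leaving out each library. Reads with any or a high BrdU fraction, the median of the surroundings, masked regions, every row per read for bins and the libraries that define candidates were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Intervals cover counting error only.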

Results

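Replication was mapped on single DNA molecules in 2 WT and 2 rrm3 libraries of budding yeast, and nascent RNA was read in 2 WT libraries. In the DNA libraries a nuclease carried by the replisome cuts the DNA where replisomes stand, so a molecule that contains BrdU and is cut at both ends holds the DNA copied by a pair of sister replisomes. Its left end was taken to mark the leftward replisome and its right end the rightward one. Not every BrdU read was shown to be such a molecule, and ends of all of them were counted. An origin candidate was spanned by 52709 of 119544 and 64198 of 143872 BrdU reads in WT. In rrm3 it was 52603 of 129064 and 66522 of 168538. RRM3 encodes a DNA helicase of the Pif1 family, known to help replication forks past tightly bound proteins such as those at tRNA genes, telomeres and the rDNA. The comparison of rrm3 with WT asks where replisomes stand more often in its absence. The DNA files held 1212021 and 1587260 reads in WT and 1290319 and 1736358 in rrm3, and the RNA files held 770410 and 2167772. BrdU was found in 12.1% ± 1.19 of nuclear reads in WT and in 13.3% ± 0.0151 in rrm3 (SD, n = 2 each).

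The rrm3 libraries lacked a stretch of chromosome 8 with about the length of RRM3. From position 163573 to 165721 (2149 bp) coverage was at most 2.15 rows per base in the rrm3 libraries, against 1139 and 1510 in WT. The gene table places RRM3 on chromosome 8 with a length of 2172 bp; its position there was not used, since the builds differ. A second stretch of chromosome 8, from 212482 to 220382 (7901 bp), was also nearly empty in rrm3, with 4.97 and 3.65 rows per base against 886 and 1258 in WT. On chromosome 13 the segment from 357001 to 375000 stood at 2.43 times the genome median in rrm3 replicate 2, at 1.24 in rrm3 replicate 1 and at 1.07 and 1.10 in WT. On chromosome 12 the segment from 1056001 to 1070000 stood at 5.31 times the median in rrm3 replicate 1, against 2.91 in rrm3 replicate 2 and 2.02 and 1.90 in WT.

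**Figure D1:**
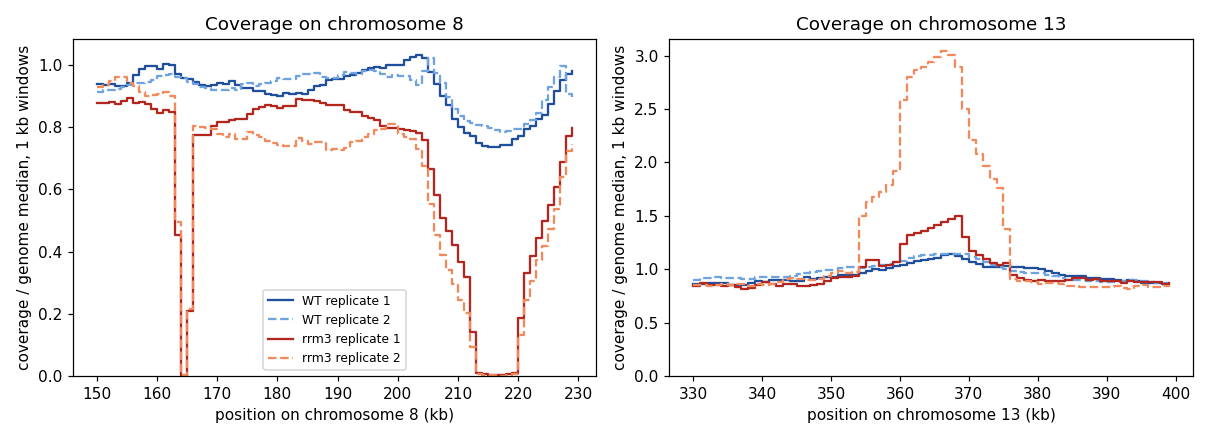
Coverage in 1 kb windows, as a multiple of the genome median, along parts of chromosomes 8 and 13 in each of the 4 DNA libraries (position in kb on the x axis). Both rrm3 libraries drop far below WT from 163573 to 165721 and from 212482 to 220382 of chromosome 8, and rrm3 replicate 2 rises to a mean of 2.43 in the chromosome 13 segment.

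Read ends, taken as the marks of replisomes, gathered more strongly at many places in rrm3 than in WT. With both directions counted together, 372 of 10151 bins of 500 bp rose in rrm3 relative to their surroundings, with a median change of 3.21-fold, and 111 of them rose over 4-fold. In WT these bins already stood a median log2 ratio of 0.32 above their surroundings, against 2.04 in rrm3. These bins held 3.06% of the read ends of BrdU reads in WT replicate 1 and 3.06% in WT replicate 2, and 10.9% and 9.61% in rrm3 replicates 1 and 2. The bins were called on these same ends, so a higher share in rrm3 follows from the choice. Few 2-fold rises were recovered in the simulated data, so the median change leans towards large rises. By direction, 236 of 4320 bins rose for left ends and 209 of 4285 for right ends. Merged over gaps of up to 1000 bp, they made 174 sites for leftward and 162 for rightward replisomes, or 294 sites in all, spread over all 16 chromosomes. Of the 174 left-end sites 41 lay within 1000 bp of a right-end site. Most bins had too few ends to test both directions. Of the left-raised bins 83 could be tested for right ends, and 37 of them were raised there too. Of the right-raised bins 67 could be tested for left ends, and 37 of them were raised there too. The filter used the mean over all 4 libraries, so a rise in rrm3 itself helped a bin to be testable. These shares may therefore overstate how often a bin rises in both directions.

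**Figure D2:**
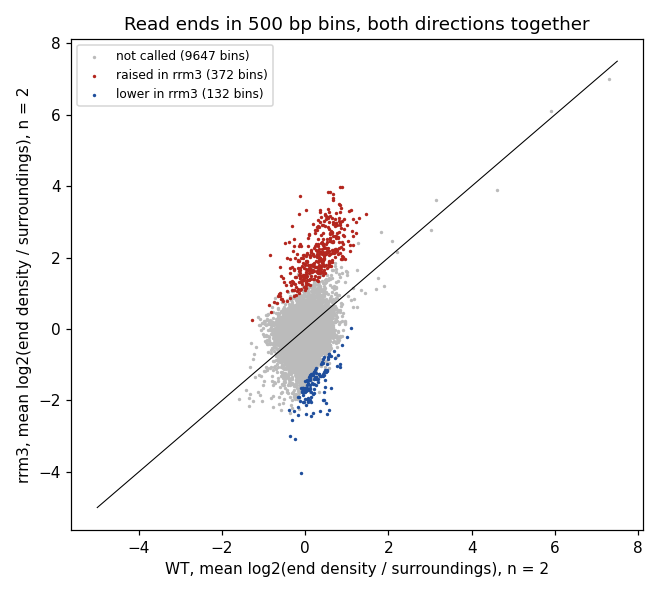
Mean log2 ratio of end density to the surroundings for each 500 bp bin, both directions together, in WT (x axis) and rrm3 (y axis), n = 2 libraries each. The line marks equal values; 372 red bins rose and 132 blue bins fell in rrm3 (limma, adjusted p below 0.05).

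For both directions together the largest rise was at 20001 to 20500 of chromosome 10, with 6 and 11 ends in WT and 59 and 91 in rrm3 (log2 change 3.83 ± 0.27 SE, limma adjusted p = 3.78e-05). It was followed by 927501 to 928000 of chromosome 16 (log2 change 3.39 ± 0.29) and 203501 to 204000 of chromosome 6 (3.34 ± 0.28). At the chromosome 6 bin 23 and 27 ends were counted in WT and 227 and 210 in rrm3. Bins at 599501 of chromosome 12 (3.27 ± 0.26) and 165001 of chromosome 1 (3.22 ± 0.26) completed the 5 largest, and 39 and 50 ends in WT stood against 392 and 416 in rrm3 at the latter. These last 4 bins shared the adjusted p of 4.99e-05.

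Left ends rose most at 927501 of chromosome 16 (log2 change 3.72 ± 0.34), with 10 and 20 ends in WT and 84 and 131 in rrm3. The next bins for left ends were at 603001 of chromosome 5 (3.70 ± 0.32), 786001 of chromosome 12 (3.66 ± 0.34), 585001 of chromosome 5 (3.62 ± 0.79) and 767501 of chromosome 13 (3.60 ± 0.40). The bin at 585001 of chromosome 5 had 0 and 7 left ends in WT and 11 and 28 in rrm3, and its size rests on the library with none: the log2 change was 1.79 without WT replicate 1 and 5.45 without WT replicate 2. Right ends rose most at 20001 of chromosome 10 (3.94 ± 0.37) and 42001 of chromosome 1 (3.79 ± 0.39), where 1 and 2 ends in WT stood against 27 and 28 in rrm3. The bins at 203501 of chromosome 6 (3.74 ± 0.37) and 599501 of chromosome 12 (3.55 ± 0.36) followed, and at both the rise for right ends was to 218 and 198 ends and to 282 and 286 ends in rrm3. The fifth, at 163501 of chromosome 8 (3.54 ± 0.37), lies at the left edge of the stretch missing in rrm3, where alignments end.

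**Figure D3:**
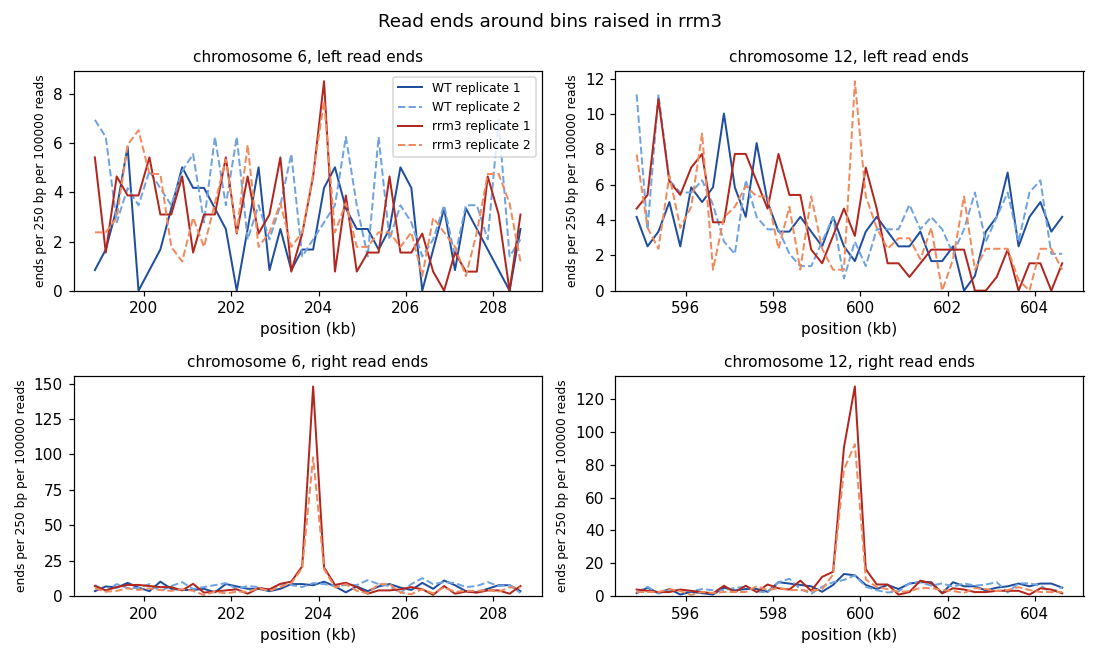
Left (top) and right (bottom) read ends per 250 bp per 100000 BrdU reads around the bins at 203501 of chromosome 6 and 599501 of chromosome 12, in each of the 4 libraries (position in kb). In both rrm3 libraries right ends form a narrow peak that is low in both WT libraries.

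In 132 bins the end density fell in rrm3 relative to the surroundings. The largest fall was at 759501 of chromosome 14, with 16 and 26 ends in WT and 3 and 1 in rrm3 (log2 change -3.93 ± 0.73, limma adjusted p = 0.00588). Bins at 377501 of chromosome 13 (-2.89 ± 0.45), 925001 of chromosome 16 (-2.86 ± 0.50), 11001 of chromosome 2 (-2.84 ± 0.60) and 12001 of chromosome 16 (-2.65 ± 0.45) followed. For left ends 108 bins fell, the largest at 759501 of chromosome 14 (-3.79 ± 0.81), at 1049501 and 1050001 of chromosome 12 (-3.43 ± 0.61 and -3.26 ± 0.64), at 924001 of chromosome 16 (-3.15 ± 0.68) and at 134001 of chromosome 1 (-3.06 ± 0.61). For right ends 84 bins fell, the largest at 11001, 11501 and 10501 of chromosome 2 (-3.04 ± 0.64, -2.78 ± 0.63 and -2.44 ± 0.61), at 567001 of chromosome 4 (-2.71 ± 0.50) and at 474501 of chromosome 5 (-2.56 ± 0.49).

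The falls, but not the rises, depended on how the surroundings were summarised. With the median of the surrounding bins in place of their mean, 371 bins rose and 11 fell, so that 97.1% of called bins were raised in place of 73.8%. For left ends the numbers were 230 and 3, and for right ends 209 and 7. In the simulated data rises were recovered more often than falls, so the shares raised may be overstated. Of the 30 named bins 13 lost their call with the median, all of them lower bins. All 15 named lower bins still had negative changes, from -2.67 at 759501 of chromosome 14 for both directions together to -0.67 at 10501 of chromosome 2 for right ends. The number of raised bins was 169 without rrm3 replicate 1 and 204 without rrm3 replicate 2, and the number of lower bins was 87 without WT replicate 1, 79 without WT replicate 2, 23 without rrm3 replicate 1 and 49 without rrm3 replicate 2. For left ends 54 bins fell without WT replicate 1 and 167 without rrm3 replicate 2. For right ends 135 bins rose without rrm3 replicate 1, and 55 fell without WT replicate 1 and 40 without rrm3 replicate 1. Leaving out a library ended no call among the named raised bins. Among the 15 named lower bins it ended 6 calls without WT replicate 1, 6 without WT replicate 2 and 3 without rrm3 replicate 1. Without rrm3 replicates 1 and 2 in turn, the log2 change for both directions together was -4.83 and -3.03 at 759501 of chromosome 14, -2.06 and -3.65 at 925001 of chromosome 16, and -2.17 and -3.51 at 11001 of chromosome 2. For left ends it was -4.70 and -2.88 at 759501 of chromosome 14, -2.02 and -4.28 at 924001 of chromosome 16, and -2.38 and -3.75 at 134001 of chromosome 1. When bins with few ends were also tested, 94 bins were raised for both directions together and limma called 0 for left or right ends apart, with 941 and 927 raised at an unadjusted p under 0.05.

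Raised bins were less often among those with the most RNA, in comparisons chosen after the bins were known. The RNA libraries were enriched for mRNA, so other transcripts, such as tRNAs, may be missed in these levels and directions. Of the 372 bins raised for both directions together 13 (3.49%) were among the top 10% of bins by RNA, against 1003 of the 9779 other bins (10.3%; Fisher's exact test, odds ratio 0.317, adjusted p = 3.36e-05 over 14 comparisons). The shares were 3.39% against 10.4% for left ends (adjusted p = 0.000611) and 3.35% against 10.4% for right ends (adjusted p = 0.0012). Of the bins lower for both directions together 3.79% were in the top 10%, against 10.1% of others (adjusted p = 0.0348). This did not hold by direction, with 6.48% against 10.1% for lower left-end bins (adjusted p = 0.4) and 9 of 84 against 420 of 4201 for lower right-end bins (adjusted p = 0.919). Among bins at or above the median RNA, the RNA ran mainly against the replisome in 16 of 64 left-raised bins (25.0%), against 1095 of 2106 other bins (52.0%; adjusted p = 0.000137). For right-raised bins it did so in 18 of 52 (34.6%) against 1035 of 2092 (49.5%), which missed the threshold after adjustment (adjusted p = 0.0715). Within 500 bp of an origin candidate lay 15 of the 372 raised bins (4.03%) and 399 of the others (4.08%; Fisher's exact test, p = 1). By the direction taken from the read end, replisomes faced away from the nearest candidate in 78.8% of left-raised and 84.7% of right-raised bins. In other bins the shares were 81.4% and 81.5% (Fisher's exact test, p = 0.304 and 0.272). Candidates were midpoint peaks of these same reads, so high shares in all bins follow from the choice.

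Windows around features were tested by class. Of 187 origin candidates tested 10 rose and 2 fell in rrm3, with the same counts when adjusted over the list alone, and the class lay above the other features (camera p = 0.000279; p = 0.278 with an estimated correlation). The risers included windows at 72251 of chromosome 15 (log2 change 1.90 ± 0.31 SE), 392051 of chromosome 11 (1.66 ± 0.32) and 556451 of chromosome 14 (1.47 ± 0.27). The windows at 469351 of chromosome 5 (-2.56 ± 0.32) and 553451 of chromosome 10 (-1.57 ± 0.33) fell. Of 25 segments near chromosome ends none rose, 6 fell and 16 had an unadjusted p under 0.05 (limma); adjusted over the list alone 1 rose and 14 fell. With limma-voom, which used the counts in the windows and left out the flanks, 4 segments were raised and 0 lower. That tests another quantity than the ratio to the flanks. The left ends of chromosomes 14 (-2.09 ± 0.31) and 9 (-1.93 ± 0.40) and the right end of chromosome 15 (-1.87 ± 0.34) fell most. That class lay below the others (camera p = 2.29e-07; p = 0.0508 with an estimated correlation), but with the median of the flanks its median change was 0.08, no segment was called and the camera p was 0.982. Of 245 windows over the segments with the highest RNA 4 rose and 2 fell (3 and 0 adjusted over the list alone), and the class did not stand apart (camera p = 0.258; p = 0.202 with an estimated correlation).

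The RNA windows that rose most were 138609 to 140828 of chromosome 1 (log2 change 1.81 ± 0.21), 171326 to 173381 of chromosome 5 (1.47 ± 0.21) and 241072 to 242000 of chromosome 12 (1.43 ± 0.21). Those at 140763 to 141689 of chromosome 8 (-1.47 ± 0.39) and 365430 to 366180 of chromosome 12 (-1.24 ± 0.32) fell. Of 387 random positions 14 rose and 6 fell, and the class lay below the others (camera p = 0.0108; p = 0.0462 with an estimated correlation). The largest changes among them were rises at 485194 of chromosome 8 (2.20 ± 0.19), 843158 of chromosome 16 (2.14 ± 0.24) and 585301 of chromosome 5 (1.99 ± 0.35), and falls at 398663 of chromosome 2 (-2.37 ± 0.39), 600970 of chromosome 5 (-1.86 ± 0.38) and 193135 of chromosome 3 (-1.46 ± 0.37). Class means per library gave an exact permutation p of 0.333 in each class, the smallest possible. Over all classes 44 features were called. When features with few ends were also tested, limma called 0 of 1504, with 147 at an unadjusted p under 0.05. The count over all classes was 1 without rrm3 replicate 1 and 2 without rrm3 replicate 2. Without WT replicate 2, 5 candidates rose and 1 RNA window fell; without WT replicate 1, limma called 0 lower RNA windows and 3 lower random positions.

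At origin candidates the peak of read midpoints over its flanks was lower in both rrm3 libraries than in both WT libraries. Candidates were chosen as midpoint peaks of these same reads, so an enrichment there follows from the choice. Random positions were kept away from candidates, so their lower values do not test it. At 197 candidates the density of midpoints within 500 bp was 6.51 and 5.14 times that 3 to 5 kb away in WT, and 3.69 and 3.32 times in rrm3 (means 5.83 ± 0.969 and 3.50 ± 0.261, SD, n = 2; exact permutation p = 0.333). Random positions gave 0.721 ± 0.0272 in WT and 0.801 ± 0.0217 in rrm3. At the candidate itself 43.5 and 35.6 midpoints per candidate and 100000 reads fell in 500 bp in WT, and 32.7 and 28.6 in rrm3. At 3 kb to the right the order was the other way, with 6.30 and 7.06 in WT and 10.5 and 9.28 in rrm3.

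By candidate, 78 were lower and 11 higher in rrm3 (limma). The largest falls were at 113251 of chromosome 15 (log2 change -2.83 ± 0.26), 167751 of chromosome 6 (-2.71 ± 0.24) and 403251 of chromosome 2 (-2.68 ± 0.30). At the first, 73 and 88 midpoints lay near the candidate in WT and 18 and 22 in rrm3. The largest rises were at 606851 of chromosome 5 (3.41 ± 0.38), 16051 of chromosome 10 (3.33 ± 0.70) and 173551 of chromosome 1 (2.05 ± 0.28). The size of the difference depended on which libraries defined the candidates. With candidates from rrm3 replicate 1 alone 26 were higher and 22 lower, and the enrichment was 4.64 and 3.77 in WT and 4.08 and 3.41 in rrm3. Without WT replicate 1 the counts were 7 higher and 50 lower, without WT replicate 2 they were 7 higher and 86 lower, and without rrm3 replicate 2 they were 12 higher and 40 lower.

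**Figure D4:**
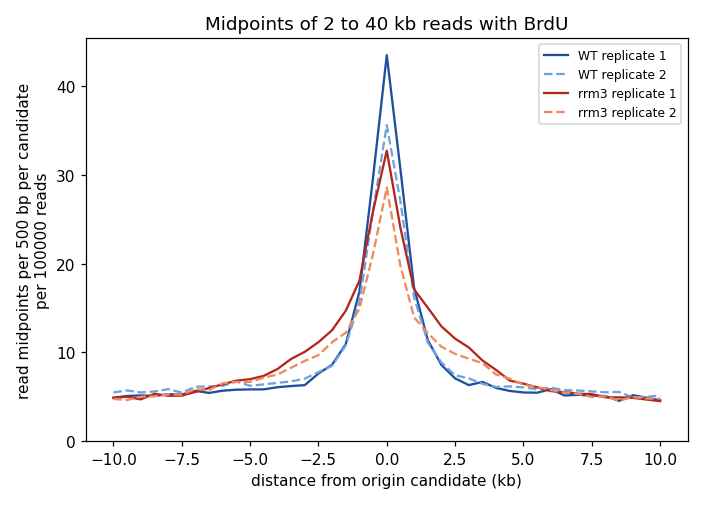
Midpoints of BrdU reads of 2 to 40 kb per 500 bp, per candidate and 100000 reads, against the distance from the 197 origin candidates (kb), in each of the 4 libraries. At 0 kb the WT libraries reach 43.5 and 35.6 and the rrm3 libraries 32.7 and 28.6, while at 3 kb the rrm3 libraries lie above WT.

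Arm lengths around an origin were compared to ask how far sister replisomes travel alike. Among reads that spanned 1 candidate, the arms lay within 1.5-fold of each other in 51.4% ± 2.23 of reads in WT and 42.9% ± 2.20 in rrm3 (SD, n = 2; exact permutation p = 0.333, the smallest possible). The median ratio of the longer to the shorter arm was 1.47 ± 0.0488 in WT and 1.67 ± 0.0617 in rrm3, against 2.63 ± 0.0269 and 2.57 ± 0.00907 around random positions. Candidates were midpoint peaks of the same reads, and a midpoint at a candidate means equal arms. The contrast with random positions therefore follows from the choice and does not show how far sister replisomes travel alike. The separation of the groups rested on the candidates used: with those from rrm3 replicate 1 alone the arms lay within 1.5-fold in 47.9% and 45.6% of reads in WT and in 47.0% and 42.7% in rrm3. The correlation of left and right arm lengths across reads did not separate the groups: Pearson's r was 0.219 and 0.140 in WT and 0.268 and 0.168 in rrm3, and Spearman's rho was 0.401 and 0.282 in WT and 0.355 and 0.302 in rrm3. Around random positions r was -0.0877 and -0.123 in WT and -0.0313 and -0.0605 in rrm3. Reads are not independent replicates, and the exact permutation p for r over the 4 libraries was 0.667. The 4 values rest on 41973 to 55351 reads per library. For reads of 2 to 20 kb the difference in r, rrm3 minus WT, was -0.0634, against 0.0382 for all. Without rrm3 replicate 1 it was -0.0115 and without WT replicate 2 it was -0.00142.

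Read length was compared between WT and rrm3. The median length of BrdU reads was 9776 ± 1301 bp in WT and 7423 ± 429 bp in rrm3, and both rrm3 libraries lay below both WT libraries (exact permutation p = 0.333). Among reads without BrdU the medians were 10151 ± 817 bp and 4359 ± 210 bp. For BrdU reads that spanned an origin candidate they were 18792 ± 118 bp and 16620 ± 1982 bp. Whether the shorter reads of rrm3 contribute to its lower midpoint peak or less equal arms was not tested.

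On the rDNA contig right read ends of BrdU reads gathered in 2 neighbouring bins in every library, and left ends gathered in the second of these bins in rrm3. Bins from 7251 to 7500 and from 7501 to 7750 held 27.0% ± 0.795 and 18.8% ± 2.27 of right ends in WT, and 24.5% ± 0.722 and 29.0% ± 1.14 in rrm3 (SD, n = 2). Left ends in the bin from 7501 to 7750 made up 4.23% ± 0.354 of left ends in WT and 16.1% ± 1.59 in rrm3, a ratio of 3.81. In the next bin, from 7751 to 8000, left ends went from 2.24% ± 0.0804 to 6.45% ± 0.44. Left ends from 6001 to 6250 and from 6751 to 7000 were also at higher shares in rrm3, at 6.90% ± 0.398 and 5.52% ± 0.323 against 3.71% ± 0.216 and 2.79% ± 0.294. These shares rest on 25064 to 71723 ends per library and direction. RNA reads on the contig lay mainly on the minus strand, with 93.4% (95% Wilson interval 91.8% to 94.8%) of 1036 rows and 87.9% (87.2% to 88.6%) of 7952. BrdU was found in 10.8% ± 0.711 of rDNA rows in WT and in 19.1% ± 2.16 in rrm3. With 2 against 2 libraries none of these comparisons can reach a permutation p under 0.333.

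**Figure D5:**
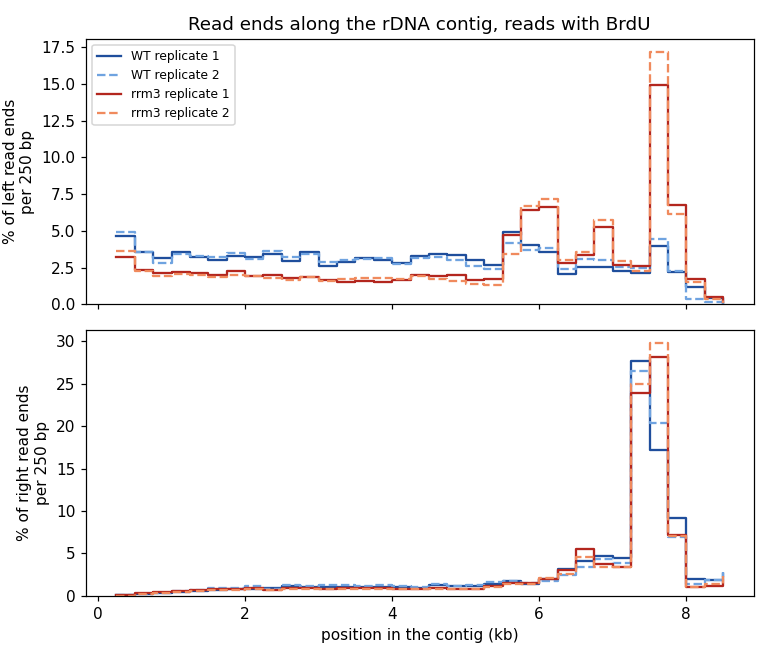
Share of left (top) and right (bottom) read ends of BrdU reads per 250 bp along the rDNA contig (position in kb), in each of the 4 libraries, without the first and last bin. Right ends peak between 7251 and 7750 in all libraries, and the left-end peak from 7501 to 7750 reaches 16.1% on average in rrm3 and 4.23% in WT.

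Transcription and replisome position were compared in the RNA segments, asking whether replisomes that meet a transcript head-on stand in it more often. The segments rest on RNA enriched for mRNA, so other transcripts may be missed. In 3828 segments the log2 ratio of head-on to co-directional ends, relative to flanks of 5 kb, did not change in rrm3 in any segment by limma, and 290 had an unadjusted p under 0.05. In the 383 segments of the top 10% by RNA the mean ratio was 0.06 ± 0.00 in WT and 0.07 ± 0.06 in rrm3 (SD, n = 2), and in the other segments 0.03 ± 0.03 and 0.04 ± 0.00. The difference between top and other segments was 0.02 ± 0.03 in WT and 0.03 ± 0.06 in rrm3 (exact permutation p = 1), and camera gave p = 0.983 for the top segments (p = 0.969 with an estimated correlation).

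Nascent RNA was seen in 5438 segments with a median of 58.9 CPM. The highest mean was at 1476395 to 1477107 on the minus strand of chromosome 4, with 8688 and 16649 CPM in the 2 replicates. It was followed by 870787 to 871984 on the minus strand of chromosome 7 (mean 9802 CPM, 13296 and 6307 in the replicates), 907716 to 908403 on the minus strand of chromosome 4 (9088 CPM) and 162246 to 163250 on the minus strand of chromosome 11 (7918 CPM). The minus-strand segment from 366299 to 366986 of chromosome 12 (7515 CPM) and the plus-strand segment from 459211 to 462577 of chromosome 8 (7396 CPM) came next. Then came segments at 329292 of chromosome 11 (6266 CPM), 152709 of chromosome 3 (5659 CPM), 233320 of chromosome 2 (5551 CPM) and 230774 of chromosome 12 (5374 CPM). The order rests on both replicates: in replicate 1 the segments at 870787 of chromosome 7 and 459211 of chromosome 8 (9015 CPM) exceeded the one with the highest mean. Replicate 2 stood at 3.75 times replicate 1 in the segment at 907716 of chromosome 4, at 2.38 times in that at 233320 of chromosome 2 and at 0.474 times in that at 870787 of chromosome 7. Across segments the replicates correlated with a Spearman's rho of 0.873, and 68.3% of segments lay within 2-fold; segments are not independent replicates.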

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

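The bins compared among reads without BrdU were chosen after the raised bins were known. Many of the bins raised in rrm3 stood higher in reads that the comparisons did not use, which is what drew attention to them. Of the 372 bins that rose in reads with BrdU, 367 had a higher end density in rrm3 than in WT among reads without BrdU, with a median log2 change of 0.52. Their median log2 ratio to the surroundings was 0.43 in WT and 0.97 in rrm3. Among reads without BrdU 151 bins were raised (limma), and 127 of them were among the 372. These reads were not shown to be uncopied DNA.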

How the results depend on the processing

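Counts below are raised then lower in rrm3. Settings on reads of any or high BrdU fraction, the median of the surroundings, masked regions, candidate definitions, and every row per read for bins were chosen after seeing the data. The planned comparisons for tRNA genes, centromeres, LTRs and gene lists were not run, since these could not be placed on the reads, and neither was the filter on mapping score, since that column of the DNA files, which no header names, was read as the BrdU fraction. Leaving out a library leaves a lone sample in one group, which is assumed to vary like the other group. Unless said, the cause of a change was not tested.

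For bins the main counts were 372 and 132 of 10151 (both directions), 236 and 108 of 4320 (left ends) and 209 and 84 of 4285 (right ends). Bins of 1 kb gave 242 raised of 7682 tested in both directions and 148 raised of 4775 tested for left ends. A pseudocount of 5 gave 284, 173 and 156 lower bins. With no filter on counts 94 rose and 0 fell in both directions, and 0 were called for left or right ends, with 23524 bins tested; 1117 raised and 893 lower bins had an unadjusted p under 0.05 by limma in both directions, 941 and 836 for left ends, and 927 and 747 for right ends. Voom on the counts in bins, without the surroundings, gave 29 and 26 lower bins for left and right ends. The next settings also changed the number of bins tested. Reads of at least 2 kb gave 222 lower of 8359 bins in both directions and 135 of 2877 for right ends. Every read gave 269 lower of 23507 bins in both directions. A BrdU fraction of at least 0.5 gave 63 lower of 1786 bins for left ends and 37 of 1645 for right ends. The median of the surroundings gave 11, 3 and 7 lower bins. Leaving out a library gave 169 to 473 raised and 23 to 87 lower bins in both directions, 186 to 282 and 54 to 167 for left ends, and 135 to 254 and 40 to 90 for right ends.

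For features the main counts were 10 and 2 (origin candidates), 0 and 6 (near chromosome ends), 4 and 2 (highest RNA) and 14 and 6 (random positions). A window of 100 bp gave 5 and 0 for candidates, 0 lower for RNA, and 6 and 0 for random positions; one of 500 bp gave 9 raised for RNA and 15 lower for random positions. A pseudocount of 5 gave 5 lower candidates, 1 and 12 near chromosome ends, 8 and 6 for RNA and 17 lower random positions. With no filter 0 features were called in any class, with 147 of 1504 at an unadjusted p under 0.05. Voom on the counts in windows, without the flanks, gave 0 lower candidates, 4 and 0 near chromosome ends, 10 lower for RNA and 3 lower random positions. Reads of at least 2 kb gave 5 lower candidates. Reads that span a candidate gave 2 and 0 for candidates, 0 lower near chromosome ends and 9 raised random positions. Every read gave 3 and 0 for candidates, 1 lower for RNA, and 8 and 2 for random positions. A BrdU fraction of at least 0.5 gave 5 raised candidates, 2 lower near chromosome ends and 1 lower random position. The median of the flanks gave 1 lower candidate, 0 lower near chromosome ends, 7 and 1 for RNA and 2 lower random positions. Leaving out a library gave 0 to 12 and 0 to 3 for candidates, 0 to 7 lower near chromosome ends, 0 to 5 and 0 to 1 for RNA, and 1 to 14 and 0 to 4 for random positions.

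For midpoints the log2 ratio of rrm3 to WT enrichment was -0.73, with candidates from WT replicate 1 it was -0.97, with candidates from rrm3 replicate 1 it was -0.17 and with every read -0.38; leaving out a library gave -0.90 to -0.56. The counts of candidates, 11 higher and 78 lower, became 7 higher for candidates 15 kb apart, 0 higher with candidates from WT replicate 1, 26 and 22 with candidates from rrm3 replicate 1, and 47 lower with every read; leaving out a library gave 7 to 12 and 40 to 86. The difference in r of the arms, 0.0382, was -0.0634 for reads of 2 to 20 kb and 0.124 with every read, and -0.0115 to 0.0879 when a library was left out. The log2 ratio of median read length, -0.39, was -0.23 for reads of at least 2 kb and -1.09 with every read, and -0.53 to -0.26 when a library was left out. Head-on against co-directional ends gave 0 calls in all settings run. The correlation of RNA replicates was 0.881 without regard to strand. The 30 named bins kept their direction in every setting that tested them; 13 lost their call with voom, 13 with the median and 25 with no filter.

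Replicate numbers were not shown to pair the libraries: deviations of libraries with the same number correlated at 0.00426, 0.00386 and 0.0185 for both directions, left and right ends. With a replicate block the bins lower in both directions were 297, candidates 18 and 4, segments near chromosome ends 1 and 11, RNA segments 12 and 5, and lower random positions 18; other calls stayed within 1.5 times the main count. The second arm of molecules ending in a raised bin was relatively longer in rrm3 at 34 and shorter at 25 of 241 bins without the block, and at 21 and 21 of 240 with candidates from WT replicate 1. At 1566 bins that were not called and had a high unadjusted p in the bin test, limma gave 0 longer and 43 shorter second arms. For the arms, 284 of these bins had an unadjusted p under 0.05 by limma. With the block limma called 0 of the 241, with 94 at an unadjusted p under 0.05.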

Other observations

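The test of the libraries that define the candidates was chosen after its values had been seen, and the comparisons of second arms and of file sections were chosen after the raised bins were known.

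The second arm of molecules with 1 end in a raised bin was compared with the arm that ends there. For 241 bins with enough reads that reach across a candidate, the median log2 ratio of the other arm to the held arm was 0.09 and 0.10 in WT and 0.18 and 0.28 in rrm3. The second arm was the longer in 66.8% and 65.1% of these bins in WT and in 65.6% and 71.0% in rrm3. With candidates from WT replicate 1 alone these shares were 71.7% and 67.9% in WT and 62.9% and 69.2% in rrm3. The comparison set was 1566 bins that were not called and had a high unadjusted p in the bin test. Uncalled bins with a lower p were left out, so the set does not stand for all uncalled bins. In this set the median was 0.14 and 0.12 in WT and 0.02 and 0.12 in rrm3. The second arm was the longer in 69.7% and 68.3% of its bins in WT and in 51.9% and 59.0% in rrm3. Group means of these medians gave an exact permutation p of 0.333 at raised bins, the smallest possible, and of 0.667 in the comparison set.

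Each DNA file holds 2 or 3 sorted sections. In 321 of the 372 bins (86.3%) every one of the 5 sections of the rrm3 files lay above every one of the 4 sections of the WT files. The bins were called on the same reads, so the share is not independent evidence for them.

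A hypothesis is that many of the raised sites are tRNA genes, which could not be placed on the reads. If so, chromosomes with more tRNA genes per Mb may have more raised sites per Mb. Over the 16 chromosomes Pearson's r was 0.778 (two-sided permutation p = 0.0005, adjusted p = 0.001 over 2 relations) and Spearman's rho 0.735 (p = 0.00163). Without the 2 chromosomes farthest from the median, r was 0.699 (permutation p = 0.00571). The number of protein-coding genes per Mb gave r = -0.411 (permutation p = 0.116, adjusted p = 0.116), rho = -0.606 (p = 0.0147) and, without the 2 farthest chromosomes, r = -0.649 (permutation p = 0.0136), so a rise with gene density is argued against. The relation is between chromosomes and does not show that any one site is a tRNA gene. Sites were divided by chromosome length, but could be called only in bins with enough ends to test. The number of such bins per chromosome was not taken into account.

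Bins lower in rrm3 may owe their call to their surroundings, because a strong peak nearby raises the mean of the surroundings. With the median of the surrounding bins 11 lower bins were called in place of 132, 10 of them among the 132, as that explanation needs. Another explanation is that fewer replisomes arrive beyond a raised bin. Of the lower left-end and right-end bins still called with the median, 5 lay within 5 kb of a raised bin of the same direction, and 4 of them (80%) lay beyond it, too few to decide.

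The lower enrichment of midpoints at candidates in rrm3 may owe part of its size to the definition of candidates. With candidates from rrm3 replicate 1 alone, the ratio of rrm3 replicate 2 to WT replicate 2 was 0.903 (95% interval 0.873 to 0.935 from counting error), against 0.646 with candidates from all libraries. Its log2 of -0.15 was smaller in size than the largest difference between replicates under that definition (0.30), so the definition stays open as the whole cause. An arm held at a raised bin could also shift midpoints away from an origin: the ratio of rrm3 to WT was 0.605 at the 161 candidates with a raised bin within 20 kb and 0.652 at the 36 without one. This log2 difference of 0.11 was less than the largest difference between replicates (0.35), so the test leaves this open too. A contribution of the shorter reads of rrm3 was not tested.

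The chromosome 13 segment from 357001 to 375000 was raised in rrm3 replicate 2. If more of it had been copied by the time of collection, the rise could be limited to rows with BrdU. Among rows without BrdU it stood at 1.80 times the highest other library, so the rise was not limited to rows with BrdU. Since reads without BrdU were not shown to be uncopied DNA, this does not decide whether more of it had been copied. A single section of the file is argued against too, since the lowest of the 3 sections stood at 1.91 times the highest other library. A gain of the segment in part or all of the cells of that culture may be a candidate explanation; no test of it was run, and rrm3 replicate 1 stood at 1.24 times the genome median against 1.07 and 1.10 in WT.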
